A study of Mus musculus with 16 samples.

How the data were processed

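Total RNA was extracted from whole E7.5 embryos or from sorted cells with a miRNeasy column kit and Trizol-LS, per the labels' protocols. Complementary DNA was made with the SMART-Seq v4 Ultra Low Input kit, which primes on poly(A) tails and does not mark strand, and libraries were made with Nextera XT. Per the submitters' processing notes, reads were checked with FastQC 0.11.5 and aligned to mm10 with STAR 2.7.0f. The read counter, the gene annotation and the normalising tool are not given in the sources used here. The authors deposited for each stage a table of normalised signal, 24421 genes with gene counts divided by 1 factor per library, and not coverage along the genome. They also deposited tables of selected genes, which give per gene the mean normalised signal, the log2 fold change and its standard error, a test score (the fold change over its standard error) and an unadjusted and an adjusted p-value, per the file headers. Every gene in them has an unadjusted p-value below 0.05 in the authors' deposited tables. Those tables were used only for comparison, and the E7.5 list of lower genes was not used here.

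In every library the low values were whole multiples of the worth of 1 read, and 100% of values came out as whole reads within 0.01 of a read. This gave the depth of each library, from 4912827 reads (E7.5 KO1) to 14861728 (E9.5 WT2). A count of 0 in a single library allows up to 3 reads, which is 0.202 to 0.611 RPM over these depths. Intervals of read counts are 95% exact Poisson intervals. A fold against a group at 0 is a lower bound, taken from 3 reads over the whole group.

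Groups were taken from the sample titles, as stage and genotype, and each stage was tested on its own because each table was normalised separately. The values were analysed as log2(value + 1), genes with a mean deposited value below 10 were left out, and KO was compared with WT by limma 3.58.1 (trended empirical Bayes, R 4.3.3) with Benjamini-Hochberg adjustment at 0.05 and no further covariate. The main test was limma's moderated test throughout, two-sided. EdgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 were run on the recovered whole reads as alternatives. An adjusted p that DESeq2 left undefined was kept undefined. The groups of libraries were also compared for overlap of their values gene by gene. Gene lists, 48 of them, were fixed before the data were examined, as were the design, the first set of alternatives and the rule for naming genes, and lists with at least 5 tested genes were tested by limma's camera with a preset correlation of 0.01. Adjusted p-values of lists run over all lists of a stage. Camera was repeated with the correlation estimated from the data, and fry was run, which tests whether a list's genes move 1 way on balance and does not compare them with other genes. Within each list, genes were also adjusted over the list alone.

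Genes were named by rule. The rule took the measured genes of the miR-302 locus, then among genes past the threshold whose groups did not overlap, whose higher mean reached 50 and whose symbols were not placeholder names, the 8 with the most positive and the 8 with the most negative log2 fold change. Where too few passed, places were filled by unadjusted p-value. It further took up to 4 members with the smallest unadjusted p-value of each list described, and 7 genes set in advance where tested. It named 39 genes at E7.5, 68 at E8.5 and 86 at E9.5. Which lists to describe was chosen after their values were seen. Some genes that the rule named are not reported here.

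Symbols were matched to GENCODE M21 (GRCm38, the assembly also called mm10). Of the 24421 symbols 23334 matched a current symbol and 667 an older one, 42 were shared by several genes and 378 were not matched. Longest annotated 3′UTRs were available for 20099 genes, of which 612 held an 8mer match to the miR-302 seed (AGCACTTA) and 3655 a 7mer (AGCACTT or GCACTTA) or 8mer match. Genes without an annotated 3′UTR counted as not searched. Seed-match genes were tested by camera within a stage, with adjustment over 6 tests. Each heptamer of the 3′UTRs was ranked by its t value in a regression of log2 fold change on its presence, log10 3′UTR length and 3′UTR GC content, in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. Figures were drawn with matplotlib 3.10.9.

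The alternatives tried were other pseudocounts (8 and 0.1), a minimum mean of 100 and no minimum, an adjusted p threshold of 0.1, quantile normalisation, rescaling with TMM factors, the count tests, the shortest in place of the longest 3′UTR, a block for the replicate number, the libraries of 1 code number only at E7.5, an estimated correlation, fry, and each library left out in turn. Alternatives added after the data were seen removed from each library a loess trend (span 0.3) over transcript length and GC content, set the code numbers 163 and 169 against the others as a block at E8.5, or left out KO1 and KO2 at E8.5. At E8.5 the statistics were recomputed over all 35 splits of the 7 libraries into groups of 3 and 4.

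The tests of single genes were checked on simulated counts drawn from the real libraries' means and depths, with 200 genes changed. At E7.5, where 12271 simulated genes were tested, limma recovered 4 of 70 genes changed 2-fold, 41 of 70 changed 4-fold and 57 of 60 changed 8-fold, and called 18 unchanged genes. At E8.5 (12103 genes) it recovered 10, 53 and 58 and called 11 unchanged genes, and at E9.5 (11633 genes) 2, 27 and 35, with 4 unchanged genes called. On the same simulated reads edgeR recovered 4, 42 and 57 genes at E7.5, 11, 55 and 58 at E8.5 and 3, 29 and 38 at E9.5, and called 20, 10 and 4 unchanged genes. DESeq2 recovered 6, 46 and 57 at E7.5, 24, 62 and 59 at E8.5 and 14, 39 and 48 at E9.5, and called 24, 33 and 44 unchanged genes. Unchanged genes made up more than 5% of the calls of each of these tests at each stage. A log2 shift of 0.3 planted in simulated counts on the genes with an 8mer match was called by camera with the preset correlation, by camera with an estimated correlation and by fry at each stage, and none of these called the genes without the shift. Simulated genes were drawn independently and without a length trend, whereas the real 8mer genes had an estimated correlation of 0.048 at E8.5. The planted shift also exceeded the 0.16 seen there. This check therefore cannot decide between the preset and the estimated correlation. A shift of 0.3 planted in simulated fold changes of genes with the seed heptamer brought that heptamer to rank 1 at each stage.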

Results

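RNA was sequenced from wild-type (WT) mouse embryos and from embryos lacking miR-302 (KO), a cluster of microRNAs best known from pluripotent cells and the early embryo. Per the series' design text, both genotypes were examined at embryonic day 7.5 (E7.5), E8.5 and E9.5, and its title places the question in neural crest development. The neural crest is a migratory population that leaves the dorsal neural tube and forms neurons, glia, pigment cells and facial skeleton. Whole C57BL/6 embryos were used at E7.5. Cells marked by Wnt1-Cre were sorted by flow cytometry at E8.5 and Sox10-positive cells at E9.5. There were 2 WT and 2 KO libraries at E7.5, 3 WT and 4 KO libraries at E8.5, and 2 WT and 2 KO libraries at E9.5. A further E8.5 KO library (KO4_5s) was not analysed here. Nothing in the labels says which libraries came from separate animals or litters, so the p-values measure the spread between these samples only. At E7.5 the libraries held 4912827 to 9184436 gene-assigned reads, at E8.5 9008784 to 13517860, and at E9.5 7300598 to 14861728. Replicate libraries all differed by more than sampling noise, with a chi-square per gene of 9.0 to 109 across pairs. Levels below are the authors' normalised read counts, given as mean ± SD over libraries, and fold changes were taken on the log2(value + 1) scale, which understates the change of low genes. Gene positions are GRCm38 (mm10) coordinates.

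The targeted locus was examined first. Mir302a to Mir302d lie on the plus strand of chromosome 3, from 127545228 (start of Mir302b) to 127545689 (end of Mir302d), in an intron of Larp7, which runs from 127536714 to 127553349 on the minus strand. At E7.5 the 2 WT libraries held 39 reads over these precursors, 14 in WT1 (95% exact Poisson interval 7.65 to 23.5) and 25 in WT2 (16.2 to 36.9). The KO1 and KO2 libraries held 0 reads. The WT level was 2.59 RPM (reads scaled to library size), and 0 reads in KO allow up to 0.219 RPM when 3 reads are taken over the group, so the precursors were at least 11.8-fold lower in KO. Mir367, the neighbouring microRNA gene, had 0 and 3 reads in the WT libraries and 1 read in each KO library, too few to compare. At E8.5, 1 read fell on the 4 precursors, in WT1_5s, and at E9.5 1 read, in WT2. The remaining libraries of both genotypes had 0, so a genotype difference was not detectable at this depth at either later stage, and the labels could be checked at E7.5 only. Mature microRNAs were not measured. Larp7, a host gene whose sense reads cannot be told from antisense reads in unstranded libraries, had log2 fold changes of -0.55, -0.02 and -0.15 at the successive stages. It passed the limma threshold at none of them when all libraries were used. At E9.5 its direction turned on the KO library used, with a log2 fold change of 0.44 without KO1 and -0.74 without KO2. Intervals and limits of this kind cover counting error only.

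**Figure D1:**
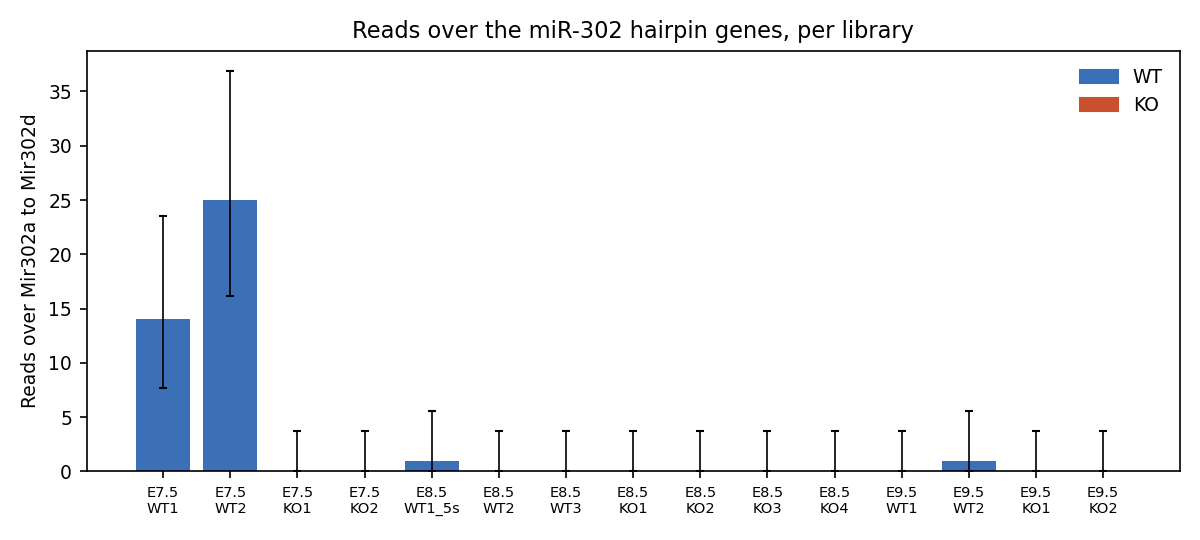
Reads over Mir302a to Mir302d in each library (bars, whole reads recovered from the normalised counts; error bars, 95% exact Poisson intervals), by stage and genotype. The WT libraries at E7.5 held 14 and 25 reads and the KO libraries 0, while no library at E8.5 or E9.5 held more than 1.

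In whole embryos at E7.5 no gene passed the limma threshold, and among the named genes those of the placenta stood higher in KO and those of the uterine lining higher in WT. Prl3d1 (ENSMUSG00000057170.6, chromosome 13, 27094190 to 27100258, plus strand), the placental lactogen of trophoblast giant cells, stood at 6172 ± 2535 in WT and 34311 ± 14199 in KO (SD, n = 2 each), 5.55-fold higher. Prl5a1 stood at 220 ± 167 and 1904 ± 749 (9.81-fold), Prl7a1 was 7.91-fold higher, and Psg22, a pregnancy-specific glycoprotein, stood at 105 ± 104 and 1088 ± 348 (13.9-fold). Plac1 was 3.14-fold higher, at 839 ± 257 against 2582 ± 357, and Plet1, a marker of early trophoblast, 3.22-fold higher. In the other direction, Ltf (lactotransferrin, a secreted product of uterine epithelium) stood at 56.2 in WT1 and 1310 in WT2 but at 1.39 and 0.801 in the KO libraries. Prss29 and Prss28, serine proteases of the uterine gland, stood at 139 and 6058 and at 31.6 and 2300 in WT, against KO means of 4.68 and 0.401. Clu (clusterin) stood at 661 and 7498 in WT and at 93.2 and 110 in KO. The membrane proteins Tmem176a, Tmem176b and Ifitm3 were 5.04-fold, 4.16-fold and 3.25-fold lower in KO, and the tight-junction gene Cldn10 was 11.8-fold lower. The giant cell lactogens Prl3d2 (5.29-fold) and Prl3d3 (5.03-fold) are close copies of Prl3d1, as Prl2c2 (8.35-fold) has close copies of its own, and their values are uncertain where reads could be shared.

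Limma called 0 of 12492 genes at E7.5 (smallest adjusted p = 0.850), although 385 had an unadjusted p below 0.05, of which 272 were higher and 113 lower in KO. On the recovered whole reads, edgeR's quasi-likelihood test also called 0 genes (399 below 0.05 before adjustment). DESeq2 called 34 genes, 21 higher and 13 lower, among them Prl5a1 (adjusted p = 4.9e-06), Prl3d1 (6.6e-06), Psg22 (7.7e-06) and Plac1 (0.00384). The KO and WT libraries did not overlap for 28.7% of genes, where chance gives 33.3%. The limma count moved to 24 without WT1, 12 without WT2, 38 without KO1 and 17 without KO2, fits in which a lone library is assumed to vary like the pair it is set against. Of the genes fixed in advance for their reported link to miR-302, none passed the threshold at this stage. The log2 fold change was 0.01 for Cdkn1a (the p21 cell-cycle inhibitor), -0.55 for Fgf15, 1.05 for Lefty1, 1.19 for Lefty2 and 0.56 for Sox9.

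**Figure D2:**
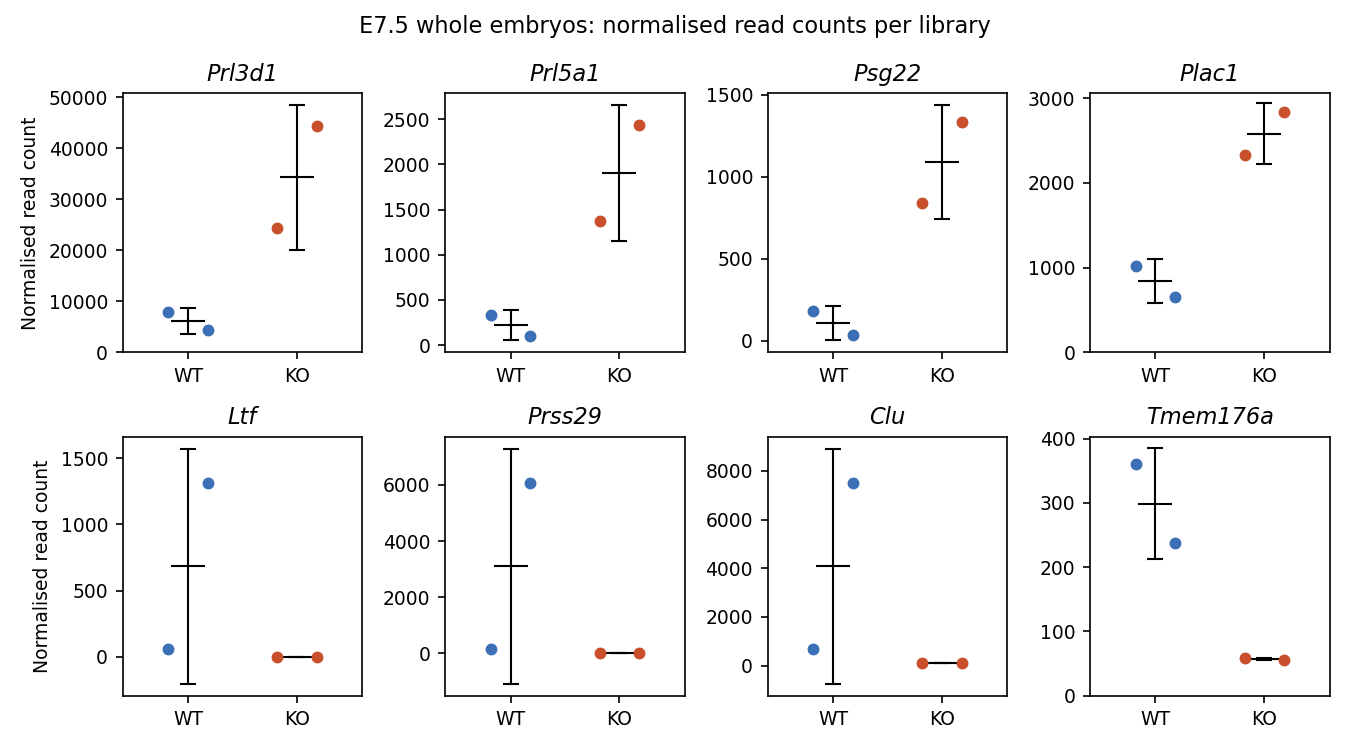
Normalised read counts of 8 genes in the 4 E7.5 libraries (dots, 1 per library; lines, mean ± SD by genotype). The placental genes Prl3d1, Prl5a1, Psg22 and Plac1 are higher in both KO libraries, and Ltf, Prss29 and Clu vary more between WT1 and WT2 than between the KO libraries.

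Of 44 gene lists tested at E7.5, limma's camera called 2, both higher in KO, and 0 with an estimated correlation between genes. It called 8 without WT1, 11 without WT2, 13 without KO1 and 5 without KO2. The genes of the primitive streak and early mesoderm, the cells that ingress at gastrulation, stood higher as a group (24 genes, median log2 fold change 0.45, 19 of them positive, adjusted p = 0.0198). The adjusted p with an estimated correlation was 0.956. None of its genes passed the limma threshold over all genes, and 0 did when adjusted over the list alone. The smallest p-values in it belonged to Mixl1 (2.31-fold higher), Mesp2 (2.37-fold) and Evx1 (2.73-fold), all transcription factors of the streak, and to Bmp4, with a log2 fold change of -0.92. The median was 0.95 without WT1 (adjusted p = 0.0147) and 1.30 without KO1 (2.7e-11), but 0.0043 without WT2 (adjusted p = 0.461) and 0.12 without KO2, where the test pointed the other way (adjusted p = 0.574). It was 0.33 with each library's transcript length and GC trend removed (adjusted p = 0.230). The list of extraembryonic ectoderm and trophoblast, the tissue that builds the placenta, also stood higher (16 genes, median 0.41, 11 positive, adjusted p = 0.0459, and adjusted p = 0.956 with an estimated correlation). Over all genes 0 of its members passed, and adjusted over the list alone 4 did, namely Prl3d1, Plac1, Prl2c2 and Rhox9 (2.92-fold). Without KO1 its median was 0.96 (adjusted p = 6.7e-08). Its call was lost without WT1 (median 0.48, adjusted p = 0.241), without WT2 (0.29, 0.306), without KO2 (-0.11, 0.396), under quantile normalisation (0.39, 0.0517) and with the length and GC trend removed (0.25, 0.390).

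Several lists of direct interest were not called at E7.5. The list of reported miR-302 family targets had a median of 0.11 (22 genes, 14 positive, adjusted p = 0.268), with Akt1, a growth-signalling kinase, 2.14-fold higher, Mbd2, a methyl-DNA binding protein, 1.91-fold higher, Lefty2 2.29-fold higher and Arid4b at a log2 fold change of -0.60. The pluripotency and epiblast list had a median of 0.09 (20 genes, adjusted p = 0.704). Within it Trim71, a stem-cell RNA-binding protein, had a log2 fold change of 1.05, Nanog of -0.78 and Dppa4 of -1.08. The sex-linked list had a median of -0.18 (5 genes, adjusted p = 0.487). Xist, expressed from the inactive X chromosome, and the Y-linked Ddx3y stood at 412 and 351 in WT1, so that both were present in that library, at 1055 and 5.03 in WT2, at 296 and 6.96 in KO1 and at 8.81 and 335 in KO2.

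In Wnt1-Cre cells at E8.5 no single gene passed the limma threshold either. The p53 target Ccng1 (cyclin G1, ENSMUSG00000020326.7, chromosome 11, 40748552 to 40755311, minus strand) stood at 164 ± 24 in 3 WT libraries and 514 ± 85.7 in 4 KO libraries, 3.10-fold higher. Ednrb, the endothelin receptor that crest cells need to migrate as melanocyte and enteric precursors, stood at 166 ± 18.7 and 550 ± 178 (3.20-fold). Fgf15, a growth factor of the neural tube, stood at 635 ± 220 and 1476 ± 503 (2.32-fold), and Dazap2 at 1096 ± 330 and 2804 ± 747 (2.57-fold). Further genes higher in KO were Slc19a2 (a thiamine transporter, 3.06-fold), Stmn3 (stathmin 3, 2.73-fold), Smarcd3 (a BAF complex subunit, 2.44-fold), Ddias and Os9 (2.33-fold each) and Thtpa (2.28-fold). Lower in KO were Phlda1, at 1640 ± 132 against 584 ± 159 (2.89-fold), Ppp4r2, a phosphatase subunit, at 1034 ± 143 against 418 ± 63.0 (2.48-fold), and the pluripotency factor Nanog, at 175 ± 14.0 against 55.1 ± 28.0 (3.41-fold). The Wnt receptor Fzd2 was 1.93-fold lower, Ccdc85c 3.15-fold, the mitochondrial leucyl-tRNA synthetase gene Lars2 3.04-fold, Pcsk1n 2.88-fold and Zswim6 2.20-fold.

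Limma called 0 of 12257 genes at E8.5 (smallest adjusted p = 0.256), with 742 below 0.05 before adjustment, 385 higher and 357 lower in KO. EdgeR's quasi-likelihood test also called 0 (743 before adjustment). DESeq2 called 32, 22 higher and 10 lower, among them Ccng1 (adjusted p = 6.4e-07), Ppp4r2 (2.7e-05), Ednrb (4.6e-05), Phlda1 (0.000101), Dazap2 (0.00842) and Nanog (0.0170). The genotypes did not overlap for 6.54% of genes, where chance gives 5.71%. Leaving out KO3 gave 3 limma calls, the embryonic globins Hba-x, Hbb-bh1 and Hbb-y (adjusted p = 0.00583 for each), and leaving out KO4 gave 2, Fn3krp (log2 fold change 5.87, adjusted p = 0.0325) and H2-Bl (4.39, adjusted p = 0.0272). Fn3krp and H2-Bl were picked out after their values were seen. Of the crest transcription factors set in advance, Sox9 had a log2 fold change of -0.06 (with 2162 in KO3 and 741 to 845 in the other KO libraries), Sox10 of -0.13 and Pax3 of 0.28. Cdkn1a had a log2 fold change of 1.16 (adjusted p = 0.821).

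**Figure D3:**
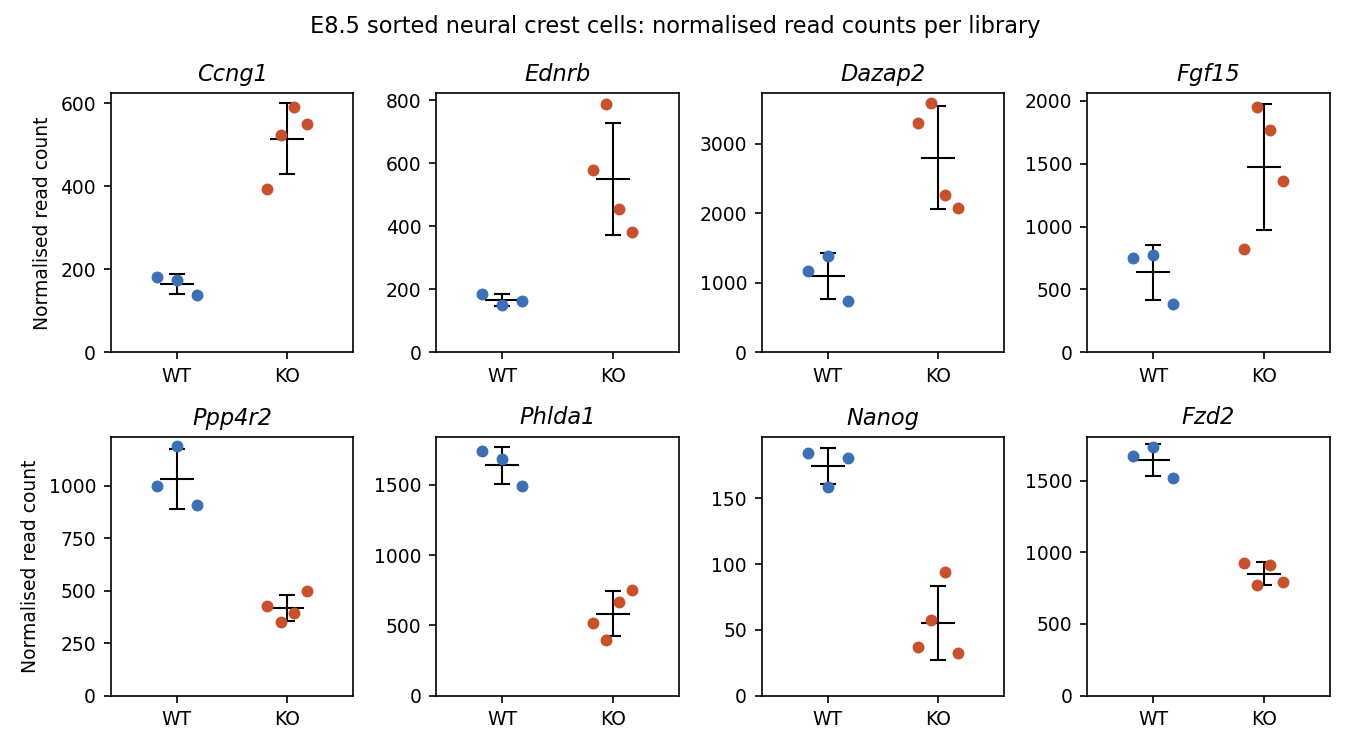
Normalised read counts of 8 genes in the 7 E8.5 libraries (dots, 1 per library; lines, mean ± SD by genotype). Ccng1 averaged 164 in WT and 514 in KO, and Phlda1 1640 and 584.

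Camera called 11 of 44 lists at E8.5, 9 higher and 2 lower in KO, and 0 with an estimated correlation, where the smallest adjusted p was 0.301. Without WT3 it called 6. In each list that follows 0 genes passed the limma threshold over all genes. The list of reported miR-302 family targets stood higher in KO (20 genes, median log2 fold change 0.29, 17 positive, adjusted p = 0.000365, and adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone 3 of its genes rose, Dazap2, Fgf15 and Ccnd1 (cyclin D1, 1.79-fold), and Suv39h1, a histone methyltransferase, was 1.39-fold higher without passing. The p53 pathway list also stood higher (21 genes, median 0.46, 15 positive, adjusted p = 0.000148, and adjusted p = 0.484 with an estimated correlation), and its median was 0.26 without KO4 (adjusted p = 0.0288). Adjusted over the list alone Ccng1 and Plk2, a stress-induced kinase (2.44-fold), rose, while Eda2r was 2.84-fold and Btg2 1.55-fold higher without passing. All 5 tested Hox genes, which mark the hindbrain and trunk levels of the axis, were higher (median 1.52, adjusted p = 1.9e-05, and adjusted p = 0.617 with an estimated correlation). Adjusted over the list alone 3 rose, among them Hoxb2 (4.52-fold) and Hoxa2 (4.93-fold). The genotypes overlapped, as the list's mean log2 level was 3.66 in WT1_5s, 5.15 in WT2 and 4.22 in WT3. It was 6.65 in KO1, 6.16 in KO2, 4.86 in KO3 and 6.48 in KO4. The immediate early genes, which respond within minutes to stimulation or cell handling, had a median of 0.41 (16 genes, 13 positive, adjusted p = 0.00024, and adjusted p = 0.695 with an estimated correlation), with Egr1 3.37-fold, Jun 2.7-fold and Egr2 5.63-fold higher and 0 genes passing when adjusted over the list alone. That call was lost without WT3 (median 0.26, adjusted p = 0.229), and without both KO1 and KO2 the median was 0.25 (0.00119).

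Markers of red blood cells had the largest median difference of the 44 lists in these sorted cells. The erythroid list had a median log2 fold change of 3.05 (3.58 with genes at 0 in WT set to their bound; 11 genes, 11 positive, adjusted p = 4.8e-07, and adjusted p = 0.756 with an estimated correlation). Adjusted over the list alone, Hba-x, Hbb-bh1, Hbb-y and Klf1, an erythroid transcription factor (1.84 against 54.2), rose. Hbb-bh1 stood at 7994 in KO1, 12529 in KO2, 0 in KO3 and 428 in KO4 and at no more than 1.35 in any WT library, and Hbb-y was at least 2035-fold higher in KO over the group. In the labels KO1 and KO2 both carry the code number 128, which no WT library carries. A batch marked by that number and the genotype cannot be told apart in them. KO4 shares the code number 169 with WT2. Without KO1 and KO2, which left 5 of its genes to test, the list was not called although its median was 3.57 (adjusted p = 0.133). The ribosomal protein genes stood lower in KO, 35 of 35 with a negative log2 fold change and with a median of -0.41 (adjusted p = 1.9e-05, and adjusted p = 0.882 with an estimated correlation). Rplp2 had a log2 fold change of -0.97, Rpl22 of -0.78 and Rps23 of -0.72, and 0 genes passed when adjusted over the list alone. The median was -0.76 without WT3, -0.25 without WT2, -0.21 without KO3, -0.11 under quantile normalisation and -0.14 with the length trend removed, all still called. The call was lost without WT1_5s (median -0.21, adjusted p = 0.0658) and with code numbers 163 and 169 of the labels set as a block (median -0.073, adjusted p = 0.524). The libraries of those codes, WT1_5s, WT2 and KO4, also stood apart in transcript length. Across genes, the Spearman correlation of a library's level, relative to the stage mean, with transcript length was -0.470, -0.392 and -0.438 in those libraries, 0.524 in WT3, 0.510 in KO3, 0.0273 in KO1 and -0.0352 in KO2.

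Of the lists of crest and mesenchymal genes, the mesenchymal ones stood higher at E8.5. Which of the sorted cells carried this rise was not tested. The mesenchymal state list had a median of 0.37 (21 genes, 16 positive, adjusted p = 0.0039, and adjusted p = 0.747 with an estimated correlation). Adjusted over the list alone Zeb1, a regulator of the epithelial to mesenchymal transition (2.60-fold), and Mmp14, a matrix protease (1.88-fold), rose and the collagen gene Col1a2 fell (1.73-fold lower), while Lum was 4.21-fold higher without passing. It was not called without WT3 (median 0.37, adjusted p = 0.141) or among genes with a mean of at least 100 (0.043, 0.592), and its median was 0.61 without KO2, 0.56 without KO3, 0.59 without KO4 and 0.59 with code numbers 163 and 169 as a block. The list of mesenchymal derivatives had a median of 0.75 (20 genes, 14 positive, adjusted p = 0.0269, and adjusted p = 0.882 with an estimated correlation), with Fli1 3.01-fold, Prrx1 2.82-fold and Dlx1 4.99-fold higher and 0 genes passing when adjusted over the list alone. Its call was lost without WT3 (median 0.42, adjusted p = 0.551), KO1 (0.43, 0.125) or KO4 (0.48, 0.356), with quantile normalisation (0.64, 0.0998) and with the length trend removed (0.76, 0.0716), and among genes with a mean of at least 100 the median was -0.0097. It was called with a median of 0.40 without WT1_5s and 0.48 without both KO1 and KO2. Crest specifiers were not called (median 0.17, adjusted p = 0.516), with Tfap2c 2.13-fold and Snai2 2.01-fold higher and Tfap2a at a log2 fold change of -0.53 and Lmo4 of -0.66. The crest migration list was not called either (22 genes, median 0.17, adjusted p = 0.18). Adjusted over that list alone Ednrb rose, and the guidance receptor Nrp1 was 1.74-fold and the cadherin gene Cdh6 1.75-fold higher without passing, with Ephb2 at a log2 fold change of -0.67.

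The other lists called at E8.5 were those of pluripotency, cholesterol synthesis and heat shock. The pluripotency and epiblast list stood lower in KO (11 genes, 4 positive, median -0.42, adjusted p = 0.0465, and adjusted p = 0.882 with an estimated correlation). Adjusted over the list alone Nanog and Fgf5, an epiblast growth factor (5.18-fold lower), fell, and the log2 fold change was -0.99 for Dnmt3b and -1.43 for Pou5f1. It was not called without WT3 (median -0.024, adjusted p = 0.485), KO1 (-0.40, 0.111) or KO4 (-0.19, 0.419), without both KO1 and KO2 (-0.51, 0.0969), among genes with a mean of at least 100 (-0.096, 0.329) or with the length trend removed (-0.31, 0.0811), and with the codes as a block its median was -0.71 (0.00172). Cholesterol synthesis genes had a median of 0.27 (20 genes, 15 positive, adjusted p = 0.00887, and adjusted p = 0.882 with an estimated correlation), with Lss 1.39-fold higher, log2 fold changes of 0.58 for Nsdhl, 0.81 for Msmo1 and 0.43 for Idi1, and 0 genes passing when adjusted over the list alone. It was not called without WT1_5s (median 0.13, adjusted p = 0.267), KO4 (0.22, 0.0788) or both KO1 and KO2 (0.11, 0.207). Heat shock and unfolded protein response genes had a median of 0.16 (21 genes, 15 positive, adjusted p = 0.0406, and adjusted p = 0.882 with an estimated correlation), with Sesn2 1.44-fold higher, log2 fold changes of 0.74 for Ddit3 and 0.48 for Herpud1, and 0 genes passing when adjusted over the list alone. Its median turned to -0.11 without WT3 (adjusted p = 0.967), and it was not called without KO1 (0.16, adjusted p = 0.0824), KO2 (0.12, 0.0737), KO4 (0.20, 0.0686), KO1 and KO2 together (0.085, 0.247), with a mean of at least 100 (0.15, 0.158) or with the length trend removed (0.16, 0.192). The median was 0.36 without WT2, 0.29 under quantile normalisation and 0.26 with the codes as a block, all called. The heat shock gene Hspa1b, at a log2 fold change of 1.59, has a near-identical neighbour and is uncertain.

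The comparison then turned from reported targets to all genes with a match to the miR-302 seed, the bases at the start of the microRNA that pair with its targets, in their longest annotated 3′UTR. At E8.5 the 424 genes with an 8mer site (AGCACTTA) had a median log2 fold change of 0.12, against -0.04 for the 9257 genes without a site. The difference of 0.16 passed the threshold of limma's camera (adjusted p = 0.000399 over the 6 tests of site class and stage) but not with an estimated correlation (adjusted p = 0.267). For the 2464 genes with a 7mer or 8mer site the difference was 0.095 (adjusted p = 0.0189, and adjusted p = 0.379 with an estimated correlation). Without WT3 the 8mer difference was 0.25, and with code numbers 163 and 169 as a block it was 0.090. It was 0.12 with each library's length and GC trend removed. Among 16371 heptamers ranked by their association with log2 fold change at E8.5, given 3′UTR length and GC content, the seed matches GCACTTA and AGCACTT took ranks 1 and 2 (t = 6.07 and t = 4.46, with 983 and 2066 genes). AGCACTT ranked 4861 at E7.5 and 4668 at E9.5. With each library's length and GC trend removed it ranked 2 at E8.5, 1474 at E7.5 (t = 2.18) and 1262 at E9.5 (t = 3.91). The 8mer difference at E7.5 was 0.0057 (adjusted p = 0.621), and it was 0.0020 without WT1, 0.044 without WT2, -0.039 without KO1 and 0.096 without KO2. With the trend removed it was 0.088, past the threshold of limma's camera before adjustment over stages. At E9.5 it was -0.90 (adjusted p = 0.00172, and adjusted p = 0.267 with an estimated correlation) and became 0.25 once each library's length and GC trend was removed. Whether the difference changed between stages was not tested.

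**Figure D4:**
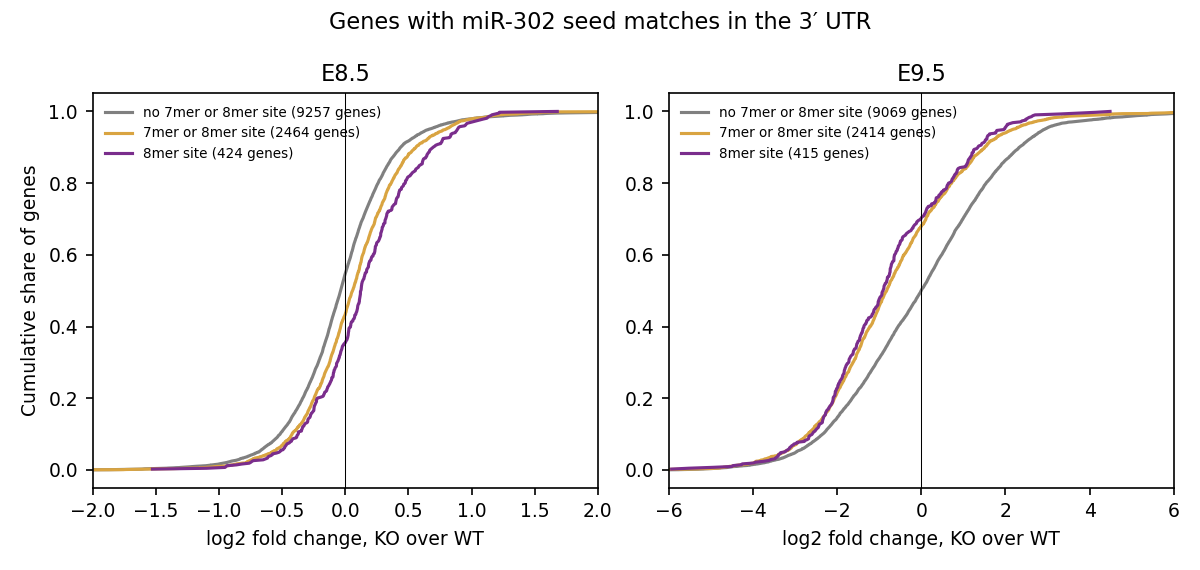
Cumulative share of genes by log2 fold change, KO minus WT, at E8.5 and at E9.5, for genes with no seed site in the 3′UTR (9257 and 9069 genes), with a 7mer or 8mer site (2464 and 2414) and with an 8mer site (424 and 415). At E8.5 the 8mer genes lie 0.16 to the right of those without a site in the median, and at E9.5 0.90 to the left.

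In Sox10-positive cells at E9.5, limma called 5700 of 12000 genes (47.5%), of which 2944 rose and 2756 fell. The 8 genes named for the largest rises were 6 transcripts made by the liver and 2 embryonic globins. Alb (albumin, ENSMUSG00000029368.10, chromosome 5, 90460897 to 90476602, plus strand) stood at 4.05 and 17.2 in the WT libraries and 1589 and 3562 in the KO libraries, 249-fold higher (adjusted p = 0.00152). The plasma protein genes Gc (log2 fold change 8.08) and Ttr (8.02), the hepatic transporter Slco1b2 (at least 108-fold) and the urinary protein genes Mup13 (7.81) and Mup2 (7.73), which are near-identical and uncertain, rose with it. The embryonic globins Hbb-bh1 and Hba-x also rose, from 0 and 2.02 in WT to 91613 in KO1 and 155 in KO2 for Hbb-bh1 (adjusted p = 0.0279), and to 57095 and 69.7 for Hba-x (0.0396). Among the genes that fell were Stk26 (161-fold lower), the lectin receptor gene Ly75 (at least 151-fold), the guidance receptor Epha3 (at least 105-fold), Taok2 (98.1-fold), Dlx3, a homeobox gene of the pharyngeal arches (70.6-fold), Dgkq (at least 68.7-fold), Tmem245 (60.8-fold) and Ret, the receptor of enteric crest precursors (at least 54.2-fold).

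Sox9, which directs crest and cartilage development, fell from 1432 ± 104 to 333 ± 176 (4.61-fold lower, limma adjusted p = 0.00909). Sox10 itself, the gene of the sort, had a log2 fold change of 0.18 (adjusted p = 0.724), Pax3 of -0.46 (0.241), Cdkn1a of 1.57 (0.0657) and Fgf15 of 1.34 (0.0541). EdgeR called 5475 genes and DESeq2 5865, and the genotypes did not overlap for 80.3% of genes, where chance gives 33.3%. The limma count was 2029 without WT1, 1920 without WT2, 8689 without KO1 and 7460 without KO2. Without WT1 the calls of Hbb-bh1 (adjusted p = 0.0698), Hba-x (0.0780) and Sox9 (0.0507) were lost, as were those of Ly75 (0.105), Epha3 (0.146), Taok2 (0.0694), Dgkq (0.215), Dlx3 (0.0817) and Tmem245 (0.0885). Without WT2 those of Stk26 (0.0714), Ret (0.229), Ly75 (0.267), Epha3 (0.309), Taok2 (0.0921), Dgkq (0.331), Dlx3 (0.121) and Tmem245 (0.136) were lost. Without KO1 the log2 fold change was 6.49 for Hbb-bh1, 5.34 for Hba-x, 0.78 for Sox10, 2.01 for Cdkn1a and 1.40 for Fgf15. Without KO2 it was 1.13 for Cdkn1a.

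The E9.5 differences followed transcript length. Across 11918 genes the log2 fold change had a Spearman correlation of -0.676 with the length of the longest transcript. With genes split by length into 5 bins of equal size, 71.5% rose in the shortest bin (up to 1723 bases), where the median was 1.77, and in the longest bin (5105 bases or more) 44.0% fell and the median was -1.65. Libraries of 1 genotype also differed along this axis, with a correlation of 0.485 for WT2 minus WT1 and -0.280 for KO2 minus KO1. With each library's length and GC trend removed, a setting added after the data were seen, 2432 genes were called (1455 higher and 977 lower). Of the 5664 called genes with a known length, 1675 were called in the same direction in that fit (29.6%) and 100 in the opposite direction. Alb stayed past the threshold (log2 fold change 7.41, adjusted p = 0.00781), and Hbb-bh1 (8.47, 0.117), Hba-x (7.75, 0.146), Tmem245 (-4.29, 0.0612), Ret (-4.45, 0.0578) and Sox9 (-1.07, 0.201) did not. In the labels both KO libraries carry the code number 171 and both WT libraries 209, so a batch marked by that number and the genotype cannot be told apart.

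**Figure D5:**
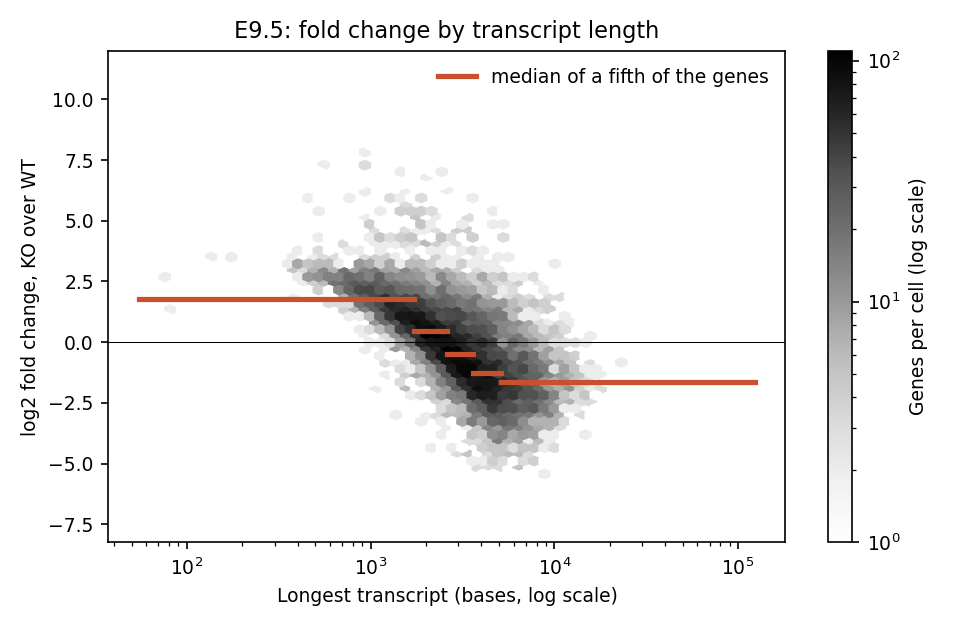
Log2 fold change, KO minus WT, at E9.5 against the length of the longest transcript in bases (log axis). Shading gives the number of genes, and horizontal lines give the medians of 5 bins of genes by length. The medians fall from 1.77 in the shortest bin to -1.65 in the longest.

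Camera called 11 of 43 lists at E9.5, 4 higher and 7 lower in KO, and 0 with an estimated correlation, where the smallest adjusted p was 0.738. Counts of list genes that rose or fell stand beside 2944 and 2756 of all 12000 tested genes. All 35 ribosomal protein genes rose, over all genes and adjusted over the list alone (median log2 fold change 2.42, adjusted p = 1.4e-13, and adjusted p = 0.738 with an estimated correlation). Rpl32 was 8.15-fold, Rps19 7.36-fold, Rplp2 7.14-fold and Rplp1 9.46-fold higher, and the median was 0.96 under quantile normalisation and 0.25 with the length trend removed, both still called. Ribosomal protein genes have many pseudogene copies, so single values are uncertain. Of 25 oxidative phosphorylation genes, which supply the respiratory chain, 19 rose and 4 fell, over all genes and adjusted over the list alone (median 1.58, adjusted p = 0.00278, and adjusted p = 0.891 with an estimated correlation), led by Ndufb5 (6.26-fold), Atp5o, Cox4i1 (5.59-fold) and Cox6c (5.81-fold). Their median was 0.39 under quantile normalisation (adjusted p = 0.475) and -0.02 with the length trend removed (0.663). With the trend removed Rplp1 (log2 fold change 0.22, adjusted p = 0.225), Cox4i1 (0.0020, 0.990) and Cox6c (0.17, 0.224) did not pass. Of 9 genes of myeloid cells and microglia, 5 rose over all genes and 6 adjusted over the list alone (median 4.40, or 3.85 with genes at 0 set to their bound; adjusted p = 0.00291, and adjusted p = 0.738 with an estimated correlation). Lyz2 (lysozyme) was at least 31.4-fold, C1qc at least 23.3-fold, Tyrobp at least 14.5-fold and Fcer1g 16.4-fold higher. The leukocyte marker Ptprc stood at 0 in both WT libraries and at 4.22 and 62.9 in KO1 and KO2. Calls of Lyz2 (adjusted p = 0.0626 and 0.0623), C1qc (0.0965 and 0.112), Tyrobp (0.174 and 0.223) and Fcer1g (0.0790 and 0.0562) were lost without WT1 and without WT2. With the trend removed the list was still called (median 2.17, adjusted p = 0.010), and the calls of C1qc (log2 fold change 3.68, adjusted p = 0.0545), Tyrobp (2.02, 0.225) and Fcer1g (1.45, 0.171) were lost.

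Transcripts of Y-linked genes were seen at E9.5 in the KO libraries only, so an effect of sex and one of genotype cannot be told apart at this stage. Of 5 genes 4 rose, over all genes and adjusted over the list alone (median 5.36, or 4.50 with genes at 0 set to their bound; adjusted p = 0.016, and adjusted p = 0.738 with an estimated correlation). Eif2s3y was at least 99.1-fold, Uty at least 23.3-fold, Kdm5d at least 22.6-fold and Ddx3y at least 21.2-fold higher, with Ddx3y at 0 in both WT libraries and at 29.6 and 54.4 in KO. Xist was present in all 4 libraries, at 161 and 248 in WT and 79.2 and 202 in KO. Without WT1 and without WT2 the calls of Kdm5d (adjusted p = 0.104 and 0.124), Ddx3y (0.109 and 0.128) and Uty (0.118 and 0.141) were lost.

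The lists of crest migration and of chromatin regulators stood lower in KO at E9.5. Of 22 crest migration genes 11 fell over all genes and 13 adjusted over the list alone (median -2.40, adjusted p = 0.00458, and adjusted p = 0.738 with an estimated correlation). The integrin gene Itgb1 was 5.40-fold, the semaphorin receptor Nrp2 11.1-fold, the cadherin gene Cdh11 5.71-fold and Ednrb 6.36-fold lower, and Ednrb was not called without WT1 (adjusted p = 0.0620). With the length trend removed the list had a median of -0.95 (adjusted p = 0.0655). Of 30 Polycomb, DNA methylation and histone modifier genes 18 fell by either adjustment, over all genes or adjusted over the list alone (median -1.47, adjusted p = 0.00108, and adjusted p = 0.738 with an estimated correlation), among them Kdm5b (5.59-fold lower), the maintenance methyltransferase Dnmt1 (5.35-fold), Bmi1 (3.48-fold) and Kdm1a (2.79-fold). Bmi1 was not called without WT1 (0.0656) or WT2 (0.0760), and the list was not called with the trend removed (-0.51, adjusted p = 0.0746). Of 23 genes of BAF and chromatin remodelling complexes 10 fell by either adjustment, over all genes or adjusted over the list alone (median -1.0, adjusted p = 0.0442, and adjusted p = 0.860 with an estimated correlation), led by Smarcc1 (5.08-fold), Chd7 (4.82-fold), Smarca5 (4.38-fold) and Smarca4 (3.69-fold). That list was not called without KO1 (median -1.46, adjusted p = 0.181), without KO2 (-1.04, 0.0820) or with the trend removed (-0.27, 0.680). Of the genes named here, Kdm5b (log2 fold change -0.80, adjusted p = 0.0739), Bmi1 (-0.89, 0.0581), Chd7 (-0.68, 0.122) and Smarca4 (-0.41, 0.123) did not pass with the trend removed.

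The other lists called at E9.5, all lower in KO, were those of the Wnt, TGF-beta and Hedgehog pathways and of mesenchymal derivatives, while the BMP (adjusted p = 0.554), FGF (0.152), Notch (0.961) and retinoic acid (0.819) lists were not called. Of 25 Wnt pathway genes 9 fell and 2 rose over all genes, and 11 and 2 adjusted over the list alone (median -1.43, adjusted p = 0.0191, and adjusted p = 0.738 with an estimated correlation). Ctnnb1 (beta-catenin) was 4.2-fold, Fzd7 8.62-fold and the secreted inhibitor gene Sfrp1 4.04-fold lower, and the inhibitor Nkd1 2.31-fold higher. Of 12 TGF-beta, activin and Nodal pathway genes 4 fell by either adjustment, over all genes or adjusted over the list alone (median -1.72, adjusted p = 0.016, and adjusted p = 0.738 with an estimated correlation), namely Smad4 (3.5-fold), Tgfbr1 (17.5-fold), Acvr2a (4.34-fold) and Acvr2b (3.12-fold). Of 15 Hedgehog pathway genes 6 fell by either adjustment, over all genes or adjusted over the list alone (median -1.60, adjusted p = 0.016, and adjusted p = 0.860 with an estimated correlation), including Gas1 (2.82-fold), Gli3 (3.45-fold), Sufu (3.94-fold) and Hhip (at least 39.7-fold). Of 23 mesenchymal derivative genes 10 fell and 2 rose by either adjustment, over all genes or adjusted over the list alone (median -2.64, adjusted p = 0.0425, and adjusted p = 0.891 with an estimated correlation). The collagen genes Col1a2 (11.8-fold), Col3a1 (10.9-fold) and Col2a1 (6.32-fold) and the receptor gene Pdgfra (12.5-fold) were lower. The Wnt and mesenchymal derivative lists were not called without KO2 (medians -0.83 and -1.28, adjusted p = 0.0820 each) or among genes with a mean of at least 100 (-1.30 and -2.25, 0.0765 and 0.0785), nor was the Hedgehog list at that mean (median -1.50, 0.151). The median was -0.89 for Wnt without WT2 (adjusted p = 0.0209) and -1.10 for TGF-beta without KO2 (0.0311). With the length trend removed the medians were -0.78 for Wnt (adjusted p = 0.127), -0.85 for TGF-beta (0.235) and -0.67 for Hedgehog (0.143), and mesenchymal derivatives were still called (-1.69). In that fit Sfrp1 (log2 fold change -0.82, adjusted p = 0.186), Acvr2a (-0.52, 0.281), Gli3 (-0.12, 0.817), Sufu (-0.82, 0.0933) and Hhip (-3.56, 0.0656) did not pass. Without WT1 the calls of Sfrp1 (0.0562), Acvr2b (0.0570), Gas1 (0.0647) and Hhip (0.284) were lost, and without WT1 and without WT2 those of Nkd1 (0.0960 and 0.0769), Acvr2a (0.0800 and 0.191), Sufu (0.0787 and 0.106) and Gli3 (0.0550 and 0.227).

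Lists that were not called at E9.5 still held genes past the threshold, as 47.5% of all 12000 tested genes were. Among 19 crest specifiers 3 rose and 6 fell, over all genes and adjusted over the list alone (median -0.56, adjusted p = 0.430). Id3 (3.92-fold) and Id2 (3.19-fold), inhibitors of differentiation, rose and Ets1 (4.94-fold) and Mycn (2.42-fold) fell, with Mycn not called without WT2 (adjusted p = 0.0678). With the length trend removed Id3 (log2 fold change 0.30, adjusted p = 0.206) and Ets1 (-0.83, 0.0731) did not pass. Among 20 reported miR-302 family targets 2 rose and 5 fell over all genes, and 1 and 3 adjusted over the list alone (median -0.39, adjusted p = 0.827). Rhoc was 7.75-fold higher, and Sox9, Arid4b (2.74-fold) and Ccnd2 (1.95-fold) fell. The calls of Arid4b (adjusted p = 0.118 and 0.122) and Ccnd2 (0.162 and 0.0682) were lost without WT1 and without WT2, and with the length trend removed their log2 fold changes were 0.16 and 0.67 and the list's median was 0.36 (adjusted p = 0.287). Of 10 visceral endoderm genes, many of which the liver also expresses, 6 rose and 1 fell, over all genes and adjusted over the list alone (median 4.83, or 4.37 with a gene at 0 set to its bound; adjusted p = 0.0544), including Fgb (88.0-fold), Apoa1 (55.8-fold) and Rbp4 (19.8-fold). With the length trend removed the list was called (median 3.12, adjusted p = 0.0176). Of 16 erythroid genes, 16 had a positive log2 fold change, 3 rose over all genes and 1 adjusted over the list alone (median 3.75, or 4.88 with bounds; adjusted p = 0.0799). The erythroid rise was mostly in KO1, as the list's mean log2 level was 0.90 and 1.22 in WT, 9.63 in KO1 and 2.06 in KO2. Hemgn was at least 74.0-fold higher and lost its call without WT1 (0.0525), and Alas2 had a log2 fold change of 5.15 (adjusted p = 0.0598).

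The authors' deposited tables of selected genes were set beside these values. At E8.5 they list 437 genes lower and 539 higher in KO, of which 8 and 18 have an adjusted p below 0.05 in the authors' deposited tables. At E9.5 they list 3282 lower and 3548 higher, 2737 and 3053 of them below that threshold. For every one of those genes the mean in the authors' deposited table equalled the mean of the normalised counts used here to within a relative difference of 1e-04, and 100% of those tested here had the same direction. Limma called 0 and 0 of the E8.5 genes and 2753 and 2944 of the E9.5 genes. The E7.5 list of higher genes in the authors' deposited table holds 3369 genes, 1701 with an adjusted p below the threshold. Its mean equalled that of the E7.5 normalised counts for 0 genes, 174 of its genes stood at 0 in all 4 libraries, and 51.1% of the 2452 tested genes had the same direction, so it was not made from the values used here.

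The last comparison asked whether the genes that differed were shared across stages. With 0 limma calls at E7.5 and at E8.5, 0 genes were called at more than 1 stage. Across genes tested at each pair of stages, which are not independent replicates, the Spearman correlation of the log2 fold changes was -0.0458 for E7.5 and E8.5, -0.0790 for E7.5 and E9.5 and -0.202 for E8.5 and E9.5. The sign was shared by 48.4%, 46.5% and 43.0% of genes. Each stage was normalised separately by the authors and drew on a different cell population, so levels were compared within a stage only.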

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

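The tests in this part were set before the results were seen, except that the lists compared between stages, and the genes named for them, were chosen after their values were seen, as were the fits with the length and GC trend removed.

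Several genes of the crest, of adhesion and of signalling stood on opposite sides of WT at E8.5 and E9.5, with every KO library on 1 side of every WT library at E8.5 and on the other at E9.5. Ednrb had a log2 fold change of 1.68 at E8.5 and -2.67 at E9.5, the cadherin gene Cdh6 0.81 and -3.41, the guidance receptor Nrp1 0.80 and -1.78, Tfap2c 1.09 and -0.50, Zeb1 1.38 and -3.39, Mmp14 0.91 and -1.75, Lum 2.07 and -0.60, and Fli1 1.59 and -3.22. The stress and growth genes Ccng1 (1.63 and -0.70), Plk2 (1.29 and -1.51), Jun (1.44 and -1.44), Sesn2 (0.52 and -1.34), Ccnd1 (0.84 and -0.24), Ddias (1.22 and -1.61) and Os9 (1.22 and -1.17) did likewise, as did Thtpa (1.19 and -0.73), Slc19a2 (1.61 and -2.70), Lss (0.47 and -0.90), and the chromatin genes Suv39h1 (0.47 and -0.71) and Bmi1 (0.74 and -1.80). Lower at E8.5 and higher at E9.5 were Nanog (-1.77 and 3.03), Lars2 (-1.60 and 3.28) and Pcsk1n (-1.53 and 3.27). As lists, the reported miR-302 family targets had medians of 0.29 at E8.5 and -0.39 at E9.5, the p53 pathway 0.46 and -0.20, and the mesenchymal state list 0.37 and -1.50, out of 60 comparisons of a list between stages. With each library's length and GC trend removed the E9.5 medians were 0.36 for the targets, on the same side as at E8.5, -0.30 for the p53 pathway and -0.96 for the mesenchymal state list.

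Between E7.5 and E8.5, Tmem176a (-2.33 and 0.89), Ccdc85c (1.34 and -1.65) and Lars2 (0.80 and -1.60) stood on opposite sides. Between E7.5 and E9.5 so did the genes lower in KO embryos first, Tmem176a (-2.33 and 2.36), Tmem176b (-2.06 and 1.64), Ifitm3 (-1.70 and 2.44), Clu (-4.45 and 3.63) and Lyz2 (-0.34, then at least 31.4-fold higher). Those higher first were Trim71 (1.05 and -3.09), Ret (0.82, then at least 54.2-fold lower), Kdm1a (0.90 and -1.48), Bmi1 (0.59 and -1.80), Smad4 (0.72 and -1.81), Acvr2b (0.67 and -1.64), Smarca5 (0.39 and -2.13), Acvr2a (0.26 and -2.12) and Chd7 (0.17 and -2.27). In all, 40 of 362 comparisons of a named gene between stages met this rule. With the length and GC trend removed 36 of the 40 had fold changes of opposite sign, and those of Ccng1, Ccnd1, Lss and Ifitm3 did not. None of these differences between stages was tested, since the stages were normalised separately and drew on different cells, and groups of 2 and 2 libraries separate by chance for 33.3% of genes. At E9.5 the groups did not overlap for 80.3% of all tested genes, and E8.5 and E9.5 shared a sign for 43.0% of genes. Many of these genes were named for groups that did not overlap or for small p-values, so their separation at that stage followed from the naming rule.

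Among the 68 named genes, 2 had a single KO library at E8.5 far from the other 3. Sox9 stood at 2162 in KO3, where the other KO libraries stood between 741 and 845, and Egr2 at 19.7 in KO4, where the others stood between 65.8 and 75.2. Chance alone marks about 1 in 20 such groups.

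In the authors' deposited table of genes higher in KO at E7.5, 174 genes stood at 0 in all 4 E7.5 libraries used here, so the list draws on values outside them.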

How the results depend on the processing

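The settings chosen only after the results were seen were removal of the length and GC trend, the block of code numbers 163 and 169 at E8.5, and leaving out KO1 and KO2 at E8.5. For the counts of genes and lists and the seed-match differences, 86 values under other settings kept their direction and side of the threshold, 32 moved by more than 1.5 times, 1 passed the threshold newly, 2 lost it and 1 reversed. For single genes and lists 3181 stayed, 142 passed newly, 177 lost their call and 6 reversed. For E7.5 genes, 0 limma calls became 34 with DESeq2, 47 with the replicate block, 17 with only the libraries of code 239 and 12 to 38 with 1 library left out. For E8.5 genes, 0 became 32 with DESeq2, 678 with the replicate block (153 higher and 525 lower) and 0 to 3 with 1 library left out. In the E8.5 replicate block KO4 had no WT library of its number and added nothing to the fold changes. At E9.5, 5700 became 2432 with the trend removed and 1920 to 8689 with 1 library left out. Of E7.5 lists, 2 calls became 4 with a minimum mean of 100 or the replicate block, 0 with an estimated correlation, with fry or with the trend removed, and 5 to 13 with 1 library left out. Of E8.5 lists, 11 became 5 with a minimum mean of 100 or the replicate block, 0 with an estimated correlation or fry, and 6 to 13 with 1 library left out. Of E9.5 lists, 11 became 6 with a minimum mean of 100, 0 with an estimated correlation and 5 with the trend removed. The 8mer difference at E7.5 was 0.088 with the trend removed, past the threshold of limma's camera before adjustment over stages. At E8.5 it stayed 0.16 but lost the threshold with an estimated correlation, and ran from 0.14 to 0.25 with 1 library left out. It was 0.12 there with the trend removed. At E9.5 the -0.90 lost the threshold with an estimated correlation and became 0.25 with the trend removed. Reversals of single values were the streak list at E7.5 without KO2 (0.12, where the test turned; 0.0043 to 1.30 over libraries left out), mesenchymal derivatives at E8.5 with a minimum mean of 100 (-0.0097), the heat shock list at E8.5 without WT3 (-0.11; up to 0.36 over libraries left out), Larp7 at E9.5 without KO1 (0.44, adjusted p = 0.0283, down to -0.74 without KO2), and Arid4b (0.16) and Ccnd2 (0.67) at E9.5 with the trend removed. A minimum mean tests fewer genes and a left-out library fewer samples, and for the other changes the cause was not tested. Replicate numbers did not pair the samples. Deviations from the group means correlated at 0.0759, -0.0248 and 0.554 for the same-numbered pairs at E8.5, where WT1_5s correlated best with KO4 (0.202) and so did WT2 (0.410). The correlation was -0.116 at E7.5 and -0.171 at E9.5, with only 2 pairs. The 2 planned settings that needed KO4_5s, adding it and a code block with it, were not run because no column held it. On the miR-302 precursors 1 read or none per library left no genotype difference to measure after E7.5, in libraries of at least 7300598 reads, deeper than E7.5 WT2 (5902254).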

Other observations

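The tests here chosen only after the result was seen were those of the uterine, trophoblast and adult liver lists, of more trophoblast tissue, of maternal sources by library, of miR-302 repression from the target list, and over splits of the number of genes called and of the sizes of list medians, and every fit with the length and GC trend removed.

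At E9.5 genes of the cell cycle differed in both directions between the KO and WT libraries, where limma called 47.5% of all 12000 tested genes. Liver, globin and myeloid transcripts were also higher in these KO libraries. A change within Sox10-positive cells therefore cannot be told apart from mixed cells. Of 24 S phase genes 13 fell and 4 rose (14 and 4 adjusted over the list alone; median -0.57, limma's camera adjusted p = 0.183). The helicase genes Mcm3 (2.98-fold) and Mcm4 (5.37-fold) and the methylation factor gene Uhrf1 (3.56-fold) fell, and the replication gene Gins2 rose (3.52-fold). Of 24 genes of G2 and M phase 13 fell and 4 rose (14 and 4 adjusted over the list alone; median -0.79, adjusted p = 0.144), where the spindle motor gene Kif11 (5.99-fold) and Top2a (4.34-fold) fell, and Birc5 (4.42-fold) and Ube2c (3.74-fold) rose. With the length and GC trend removed the medians were -0.50 for S phase (adjusted p = 0.0549) and -0.51 for G2 and M phase (0.137). All 8 genes stayed past the threshold, with log2 fold changes of -1.26 for Mcm3, -1.55 for Mcm4, -1.11 for Uhrf1, 2.72 for Gins2, -1.15 for Kif11, -0.61 for Top2a, 2.83 for Birc5 and 1.37 for Ube2c.

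Genes of the adult liver, a list drawn up after Alb was seen, stood higher in both E9.5 KO libraries. All 12 tested genes rose, with a median log2 fold change of 6.5 (6.40 with genes at 0 set to their bound). Cyp3a11, a drug-metabolising enzyme, stood at 0 and 1.01 in WT against 125 and 233 in KO, and Cps1, of the urea cycle, at 1.01 and 0.505 against 66.5 and 122. Afp, the main plasma protein of the fetal liver, stood at 0 and 0.505 in WT and at 1.06 and 0 in KO. The Sox10 sort should remove hepatocytes. With all 12 adult liver genes higher and Afp near 0, fetal liver cells as the source are argued against. No other origin of these transcripts was tested.

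Short transcripts were higher and long transcripts lower in the E9.5 KO libraries. With each library's length and GC trend removed, a fit added after the data were seen with a bound on its count written before it was run, 2432 genes were called against 5700, which is below the bound, and 1675 of the 5664 called genes with a known length were called in both fits in the same direction (100 in opposite directions). The KO libraries differed from each other along the same axis (correlation with length -0.280), which is consistent with a library or RNA quality trend. Red blood cells in the KO sorts as the whole cause are argued against, because the median ribosomal protein gene was lower in KO1, which had far more globin, than in KO2 (log2 KO1 minus KO2 -0.156, with 28 of 35 genes higher in KO2). This does not cover other admixed cells, since the mean log2 level of the myeloid list was 4.55 in KO1 and 5.44 in KO2. The code number follows genotype at E9.5, so a preparation difference and a biological difference cannot be told apart here, and the latter remains open.

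Genes with a miR-302 8mer site were higher in KO at E8.5. A bias of 3′UTR length or GC content is argued against, since AGCACTT took rank 2 of 16371 heptamers with both in the regression. Chance was not excluded, as 5 of the 35 splits of the 7 libraries gave a difference as large as the real 0.161 (highest other 0.263), and 4 splits ranked AGCACTT as near to either end as rank 2 (highest other 1, in the splits whose groups of 4 were WT1_5s, WT2, WT3 and KO1, then WT1_5s, WT3, KO1 and KO4, then WT2, KO2, KO3 and KO4). Loss of repression by miR-302 remains a candidate explanation, with the list of reported targets at an adjusted p of 0.000365 (adjusted p = 0.301 with an estimated correlation), and the split with the difference of 0.263 set WT3, KO1, KO2 and KO3 against WT1_5s, WT2 and KO4, the libraries of code numbers 163 and 169. With those codes as a block the difference was 0.090. It was 0.123 with each library's length and GC trend removed. In that setting 3 of the 35 splits, the real one included, gave a difference as large (highest other 0.151).

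Among the genes named at E7.5, none of them called by limma, those of the placenta stood higher in KO and Ltf, Prss28, Prss29 and Clu higher in WT. A single maternal source of like composition in both WT libraries is argued against, since 10 of 11 tested uterus and decidua genes outside the pattern were higher in WT1 (median log2 WT2 minus WT1 -2.51), while those 4 were higher in WT2 (median 4.98). Maternal tissue that differed between WT1 and WT2 remains open, as 8 of the 11 were lower in KO (median log2 fold change -0.713), but the decidual gene Prl8a2 was not (6897 in WT1, 294 in WT2, and 5952 and 5925 in KO). More ectoplacental cone or giant cell tissue in KO also remains open, as 6 of 7 trophoblast genes not named above, 5 of them also in the list fixed in advance, were higher (median 0.50, with the pluripotency list at 0.09), but by 0.22 in KO1 against 0.90 in KO2. With 0 genes of either list called by limma, neither can be told apart from an effect of genotype on the placenta, which was not tested.

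The other splits of the 7 libraries at E8.5 were set beside the further results. With 0 genes called by the real split, 35 of the 35 splits necessarily called as many, which says nothing of chance, and the highest other called 940. That split, and the highest count of genes below an unadjusted p of 0.05 (3439, against 742 for the real split, with 10 of the 35 splits as large), again set WT1_5s, WT2 and KO4 against the rest, which points to a structure of the samples that follows code numbers 163 and 169. With the codes as a block limma called 0 of 12257 genes, and 1257 were below 0.05 before adjustment. As many lists as the real 11 were called by 17 of the 35 splits (highest other 19). For the p53 pathway list 3 of the 35 splits gave as small a p as the real 1.34e-05 (smallest other 3.17e-08), and for the reported targets 3 of the 35 did (real 4.97e-05, smallest other 1.74e-05). Each count includes the real split. For the targets the others grouped the 3 WT libraries with KO1 or with KO2. For the p53 list they grouped the 3 WT libraries with KO1, or WT2 with KO2, KO3 and KO4. By the counts of genes below 0.05 and of lists, and by these p-values, chance was not excluded. In size of the median, a measure chosen after the result was seen, the real split ranked 1 of 35 for both lists (0.459 for the p53 pathway, highest other 0.321, and 0.293 for the targets, highest other 0.280), the smallest share the splits can give. This does not settle chance, as the p53 median was 0.26 without KO4 and the tests by p, set in advance, left it open.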
